A study of Mus musculus with 4 samples.

How the data were processed

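Gene expression was measured by RNA sequencing in 4 libraries of 32Dclone3 cells, a mouse myeloid line kept in medium with interleukin-3. Per the labels' protocols, the cells had been stably infected with a control virus or with the same vector carrying miR-125b, separate virus supernatants served the infections of each condition, and poly(A)-enriched RNA was made into Illumina libraries. Groups and replicate numbers came from the sample titles, giving 2 control and 2 miR-125b libraries. Mature miRNAs are not captured by such libraries. Whether the 2 libraries of a group also differed in the day of culture or of sequencing is not given in the sources used here.

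The authors deposited 1 table per library with 26982 rows, each a RefSeq transcript with its position, exons, exon length and an RPKM value (reads per kilobase of exon per M reads). The build was mm9 per the submitters' processing notes. The aligner, the counting program and the treatment of reads that match several places are not given in the sources used here. Each RPKM value as deposited, multiplied by its exon length, was a whole multiple of 1 step per library in 100.0% of rows (tolerance 0.001 reads), and that step equalled the inverse of the summed reads, so the reads behind each row could be recovered. The values are thus scaled by the reads assigned to rows and not adjusted further. Transcripts of 1 gene repeat shared reads in several rows, and 3423 genes had more than 1 row. The row with the longest exon length was kept for each of 21506 genes. No row lay on chromosome Y or on the mitochondrial genome. Gene names are those of the tables, in which a few symbols had been turned into dates.

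Summed over all rows, the control libraries held 11.2 and 10.4 M reads and the miR-125b libraries 12.6 and 11.7 M. Over 1 row per gene the totals were 8.42, 7.73, 9.48 and 8.82 M, in the same order. For a transcript of 1 kb, 1 read was worth between 0.0792 and 0.0964 RPKM. Rows with close copies elsewhere in the genome, such as ribosomal protein genes and Gapdh, are uncertain because reads shared with pseudogenes can be lost or divided. The labels do not say that counting used the strand, so overlapping and antisense genes cannot be told apart.

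A count test had been chosen before the data were examined, with limma in its place if no counts were given. Because the values were RPKM, the test used was limma's moderated linear model (trended prior, 2-sided) on log2(RPKM + 1), with the group as the only term. Genes needed at least 1 RPKM in at least 2 libraries, which left 10310. Adjusted p-values follow Benjamini and Hochberg, with a threshold of 0.05. Fold changes are differences on the log2(RPKM + 1) scale, which understates changes of genes with low values. With 2 libraries per group the residual had 2 degrees of freedom and the prior 4.63, and p-values measure the spread between these cultures only.

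The 23 gene lists were written before the data were examined. They cover reported miR-125b targets, neutrophil granule and granulocytic maturation genes, monocyte and macrophage, mast cell and basophil, erythroid and megakaryocyte, lymphoid, and stromal and fibroblast markers, stem and progenitor regulators, intrinsic apoptosis, the p53 response, IL-3 and JAK-STAT signalling, mitosis, DNA replication, glycolysis, the mitochondrial respiratory chain, cholesterol biosynthesis, the unfolded protein and amino acid response, the type I interferon response, the NF-kB response, the miRNA machinery, ribosomal proteins, the lysosome, and actin cytoskeleton and adhesion. Together they held 514 distinct tested genes. Some lists share members, so their shifts are not independent. For instance, Trp53inp1 and Bbc3 are in both the target and p53 lists, and Stat3 and Dusp6 in both the target and IL-3 lists. Each list was tested with limma's camera (preset correlation 0.01, adjusted over the 23 lists), and again with an estimated correlation and with fry. With an estimated correlation camera takes its p from the 2 residual degrees of freedom. A larger p there need not reflect correlation between genes, and such a test had little power here. Within each list, p-values were also adjusted over the list alone.

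Sites for miR-125b were searched in the longest annotated 3′ UTR of each gene in GENCODE M21, whose build (GRCm38) differs from that of the tables, so that only names and sequences were taken from it. Of 21506 genes, 99.0% were joined to it through RefSeq accessions or symbols. Among the tested genes, 9944 had a 3′ UTR. The seed match CTCAGGG pairs with bases 2 to 8 of miR-125b (a 7mer-m8 site). With a following A it is an 8mer, TCAGGGA is a 7mer-A1 site and TCAGGG a 6mer. Genes were assigned to their best site, and camera was run on genes with an 8mer or 7mer-m8 site among genes with a 3′ UTR. In addition, 10000 random gene lists matched on mean expression and 3′ UTR length were drawn. Each of 16020 7-mers found in at least 50 genes was ranked by z, the difference in mean log2 fold change between genes with and without it divided by its standard error over genes, after a linear correction for 3′ UTR length and GC content. Genes are not independent replicates, so z serves for ranking only.

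The rule for named genes, fixed before the data were examined, took genes past the threshold. Where fewer than 24 passed, the places went to those with the smallest p among genes at a mean of 2 or more CPM whose miR-125b libraries both lay on the same side of both controls. All measured members of the list of reported targets could be named, and of other lists up to 4 members with the smallest p. Genes named outside this rule are described as such.

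The gene test, the set test and the 7-mer ranking were tested on simulated data for this comparison. In 10 simulated sets of 10310 genes with 200 changed genes each, limma called 12.2% of 1.5-fold, 61.0% of 2-fold, 98.4% of 4-fold and 99.8% of 8-fold changes. Unchanged genes made up 11.8% of the calls, above the threshold of 5%. Of these 181 false calls, 161 were among the 783 genes with fewer than 50 reads on average. Among genes with 50 reads or more, 1.6% of calls were false. All genes were simulated with 1 dispersion (0.0234), estimated from genes with many reads, and with no GC trend in any library. The real libraries differ in both, so these shares need not hold for them. A lack of calls in the real data therefore does not show a lack of changes. With a set of 1551 genes lowered by 0.12, camera passed 0.05 in 100 of 100 simulations, and in 0 of 100 with no shift. The genes were simulated without correlation between them. How often camera passes by error in correlated lists, such as the interferon list (estimated correlation 0.893), was thus not tested. The 7-mer ranking on 9944 genes put a lowered 7-mer first in 20 of 20 simulations, and in 0 of 20 with no shift. These simulations shuffled the real fold changes among genes, which removed any link with 3′ UTR length or base composition. A 7-mer drawn at random would hardly ever rank first of 16020, so the result with no shift says little about false first ranks.

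Alternatives mostly changed 1 choice at a time, apart from combinations of the block, the GC and length corrections and a left-out library, and from limma-voom, which changed model and scaling. They were limma-voom on the recovered reads with trimmed-mean factors, the low-value filter, the pseudocount, the replicate block, GC and length corrections, the site definition, the set test, and each library left out. Scaling factors, a GC correction alone, other rows per gene and minimum lengths or levels were added after the data had been seen. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.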

Results

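The comparison asked how gene expression in 32Dclone3 cells, a mouse myeloid progenitor line that depends on interleukin-3, differed between cells carrying an empty vector and cells overexpressing miR-125b, a miRNA of haematopoietic stem and progenitor cells. There were 2 libraries per condition. Between 10173 and 10244 genes reached 1 RPKM in a library, and the 10 most abundant genes took between 3.7% and 4.0% of its reads. For a transcript of 1 kb, 3 reads amounted to between 0.238 and 0.289 RPKM, so that differences below about that level were not detectable. Intervals of this kind cover counting error only.

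The hairpin row of Mir125b-1 (chromosome 9, 41390009 to 41390085 in mm9, a noncoding transcript of 1 exon and 77 bases) held 0 reads in both control libraries and 4 reads in each miR-125b library. Counts of 0 allow up to 3 reads. No reads fell in Mir125b-2 (chromosome 16, 77646518 to 77646588) or Mir125a (chromosome 17, 17967776 to 17967843) in any library. The row of Mir223, the hairpin of a miRNA of maturing myeloid cells, held 16 and 8 reads in the control libraries and 3 and 2 in the miR-125b libraries. Actb, named outside the rule for named genes like Mir223, stood at 960.6 ± 0.112 RPKM in control and 870.1 ± 52.7 RPKM in miR-125b cells (SD, n = 2 each).

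Across genes, Pearson's r of log2(RPKM + 1) was 0.957 between the control libraries and 0.979 between the miR-125b libraries, while control replicate 1 correlated with the miR-125b libraries at 0.977 and 0.962. Control replicate 2 lay apart from the other 3 libraries on the first principal component, which held 57.8% of the variance. Its difference from control replicate 1 followed transcript GC content across genes (Spearman's rho 0.475). Neither pair of replicates was a duplicate, with chi-square values per gene of 41.4 and 16.0.

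Among genes at a mean of 2 CPM or more, those with the smallest p were mainly lower with miR-125b. Of the first 24 of these, 22 were lower and 2 were higher, and 11 of the 22 carried an 8mer or 7mer-m8 site for miR-125b in the 3′ UTR. Sec14l2, which encodes a lipid-binding protein, stood at 14.6 ± 2.73 RPKM in control and 4.04 ± 0.484 RPKM in miR-125b cells (SD, n = 2 each) and carried 2 such sites. Nrm, which encodes the nuclear envelope protein nurim and carried 3 sites, was at 15.4 ± 0.169 RPKM in control and 5.61 ± 0.108 RPKM with miR-125b. Ifitm6, which carried none, was at 20.7 ± 4.29 and 2.39 ± 1.38 RPKM. The higher genes were Matk, a kinase that phosphorylates Src family kinases, at 2.61 ± 0.307 RPKM in control and 7.85 ± 0.265 RPKM with miR-125b, and Fig4, a phosphoinositide phosphatase, at 3.42 ± 0.0906 and 8.74 ± 0.824 RPKM.

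None of these genes passed limma's test over all 10310 genes, where 0 were called. The smallest adjusted p was 0.104, reached by Mir125b-1, which has under 2 CPM, and by another gene outside the 24. Among the 24 genes the smallest adjusted p was 0.173. At an unadjusted p under 0.05 there were 967 genes, 430 higher and 537 lower, where chance gives 516. Of these, 164 differed at least 2-fold, 46 higher and 118 lower. In 42.8% of genes the groups did not overlap, against 33.3% by chance. With limma-voom on the recovered reads 0 genes were called and 1004 had an unadjusted p under 0.05. The count of 0 depended on single libraries, being 91 genes without miR-125b replicate 1, 25 without miR-125b replicate 2 and 1 without control replicate 2. The count of 967 was 3007 without control replicate 1 and 332 without miR-125b replicate 2. The share that was lower also turned, being 55.5% with all libraries, 47.9% without control replicate 1, 48.1% without control replicate 2 and 66.6% without miR-125b replicate 2, and it was 49.8% without a filter on low values, so neither direction prevailed throughout.

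The other genes named by smallest p, each with an adjusted p of at most 0.301 in limma's test, included 4930572J05Rik (chromosome 15, 74551664 to 74554803), with 2 sites and a log2 fold change of -1.73 ± 0.19 (SE), and Tnfsf4, the gene of the OX40 ligand (chromosome 1, 163325569 to 163348337), with 1 site and -1.61 ± 0.21. Npl, which encodes N-acetylneuraminate lyase, differed by -1.43 ± 0.20, Lfng, a Fringe glycosyltransferase, by -1.18 ± 0.18 and the cell-cycle transcription factor gene E2f2 by -1.09 ± 0.18, and all of these carried an 8mer. Pctp, 2310001A20Rik and Tmem123 carried a 7mer-m8 site, with log2 fold changes of -1.14, -1.13 and -1.18. Genes without an 8mer or 7mer-m8 site included Pstpip2 (-1.36), Ccl6 (-2.54), AB124611 (-1.51), Rce1 (-1.01), Cd33 (-1.19) and Mesdc1 (-1.01), of which Mesdc1 had a 6mer. All of the 24 genes kept their direction in each alternative analysis that held them, and Tnfsf4, Cd33 and Ltf were not in the one that required a mean of 5 RPKM. The genes had been chosen for groups that do not overlap. Leaving out a library could therefore not turn their direction, and this is no evidence of robustness.

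Messenger RNAs with a miR-125b site were lower as a group in miR-125b cells. The median log2 fold change was -0.069 for the 1551 genes with an 8mer or 7mer-m8 site and 0.050 for the 6329 genes with no site, a difference of -0.12 (camera p = 1.35e-04, and p = 0.060 with an estimated correlation). The difference from genes without a site was -0.17 for the 553 genes whose best site was an 8mer, -0.10 for 998 genes with a 7mer-m8, -0.023 for 711 genes with a 7mer-A1 and -0.020 for 1353 genes with a 6mer. It was -0.19 for the 278 genes with at least 2 7mer-m8 sites. Without control replicate 2 the difference was -0.062 for 8mer or 7mer-m8 sites, -0.11 for an 8mer and -0.045 for a 7mer-m8, and without a filter on low values it was -0.042, -0.051 and -0.038, in the same order. With libraries left out in turn, the difference ran from -0.051 to -0.019 for a 7mer-A1 and from -0.036 to -0.0053 for a 6mer. Of the genes with an 8mer, 62.7% were lower, against 43.9% of genes with no site.

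**Figure D1:**
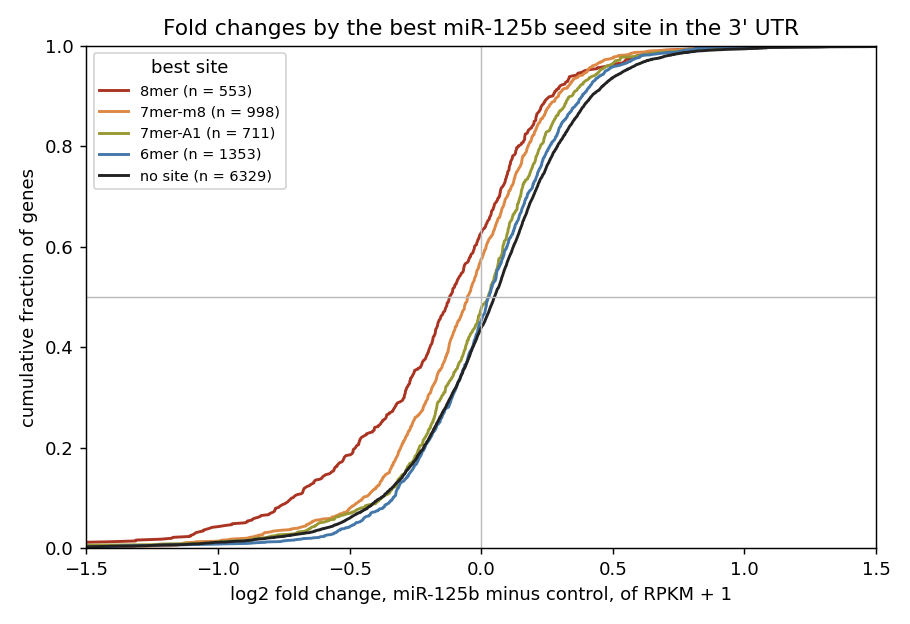
Cumulative fraction of genes against the log2 fold change of RPKM + 1 (miR-125b minus control, means of 2 libraries each), by the best miR-125b site in the 3′ UTR; each line is 1 class of genes. The 8mer and 7mer-m8 lines lie to the left of the line of genes with no site, with medians of -0.12, -0.052 and 0.050.

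Among the 16020 7-mers ranked by their relation to the fold changes after correction for 3′ UTR length and GC content, the seed match CTCAGGG was the most negative (z = -10.9). The next were TCTCAGG (z = -9.30) and TCAGGGA (z = -8.98), which overlap it. It was also first in each of the 4 pairings of a control with a miR-125b library, where z ran from -9.31 to -8.50. In the pairings within a group its rank was 14940 for the controls (z = 1.95) and 18 for the miR-125b libraries (z = -2.75). Sites for other miRNAs ranked between 10270 and 16011 from the most negative, with let-7 lowest and miR-142-3p highest of let-7, miR-223, miR-155, miR-142-3p, miR-16 and miR-21. The sites of the passenger strands of miR-125b-1 and miR-125b-2 ranked 1969 and 11924. None of 10000 random lists matched on expression and 3′ UTR length had a median as low as the genes with an 8mer or 7mer-m8 site, the lowest being -0.0017.

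**Figure D2:**
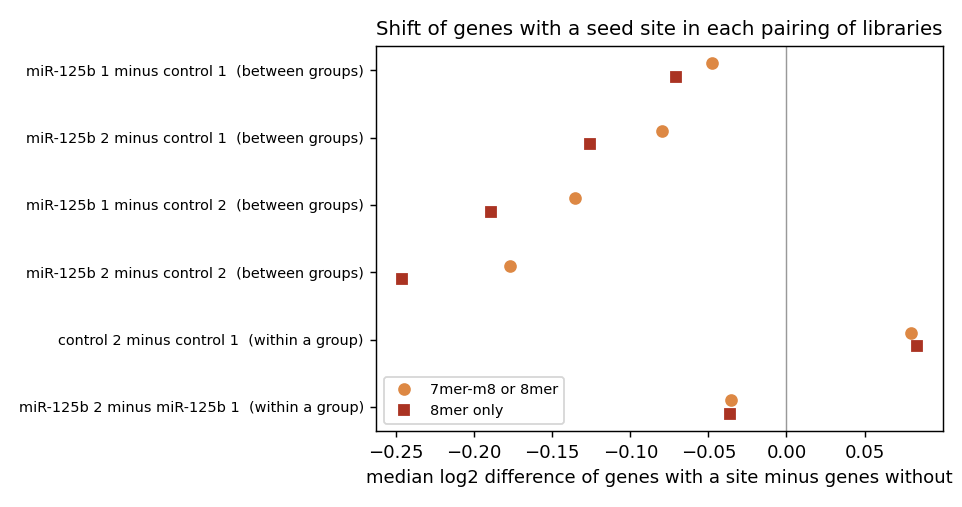
Difference in the median log2 RPKM + 1 between genes with and without a miR-125b site (horizontal axis) for each pairing of single libraries, for 8mer or 7mer-m8 sites (circles) and 8mer sites only (squares). The 4 pairings between groups lie between -0.047 and -0.18 for the circles, and the pairings within a group at 0.080 and -0.036.

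No gene was called over all genes, so the planned share of called genes with a site could not be given. Genes at an unadjusted p under 0.05 were used in its place after the data had been seen. An 8mer or 7mer-m8 site was present in 168 of 495 such lower genes (33.9%), in 38 of 411 such higher genes (9.2%) and in 1345 of 9038 other genes (14.9%). The odds ratio of lower against higher genes was 5.04 (2-sided Fisher's exact test across genes, p = 8.82e-20), and genes are not independent replicates. The odds ratio was 2.94 without control replicate 2 and 3.28 without miR-125b replicate 2, and 7.80 with genes at 5 RPKM or more.

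Genes reported as miR-125b targets were lower as a group, with a median log2 fold change of -0.31 over 32 tested members (camera adjusted p = 1.71e-04). Without a filter on low values the median was -0.18 over 40 members. With an estimated correlation, -0.019 in this list, camera's p was 0.040 before and 0.594 after adjustment over the 23 lists. The adjusted p with fry was 0.391. The median of the targets was below that of the controls in 4 of 4 pairings of libraries. At an unadjusted p under 0.05, 8 members were lower, 1 was higher and 23 did neither, and over all genes 0 passed. Adjusted over the list alone, 4 members passed and all were lower. Arid3a, a DNA-binding protein gene of chromosome 10 (79389817 to 79417757) with 6 7mer-m8 sites of which at least 1 is an 8mer, stood at 11.1 ± 0.101 RPKM in control and 4.22 ± 0.666 RPKM in miR-125b cells (SD, n = 2 each). Abtb1, with 1 8mer, stood at 19.5 ± 9.03 and 5.01 ± 0.483 RPKM. The p53-inducible gene Trp53inp1, with a 7mer-m8 site, was at 12.2 ± 3.35 and 4.88 ± 0.897 RPKM, and the kinase gene Map3k11, with an 8mer, at 19.3 ± 6.07 and 8.56 ± 0.659 RPKM. Some members may have been reported from these same cultures, so the list's direction is not wholly independent evidence.

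Among the other reported targets, the apoptosis gene Bak1 was at 68.2 ± 1.36 RPKM in control and 48.4 ± 7.72 RPKM with miR-125b, and Mcl1, an anti-apoptotic relative, was at 211.9 ± 11.7 and 145.5 ± 7.13 RPKM. Log2 fold changes were -0.46 ± 0.24 (SE) for Stat3, -0.95 ± 0.30 for Zfp385a, -0.72 ± 0.20 for Dusp6 and -0.38 ± 0.21 for Cbfb. With libraries left out in turn they ran from -0.75 to -0.18 for Stat3, -1.31 to -0.59 for Zfp385a, -0.57 to -0.18 for Cbfb and -1.71 to -0.29 for Bbc3, and that of Tnfaip3 from 0.44 to 0.92. Bbc3 was at 29.2 ± 19.5 and 12.6 ± 2.44 RPKM. Trp53 differed by -0.073 ± 0.18. Tnfaip3, which has an 8mer, was higher, at 6.80 ± 1.83 RPKM in control and 11.4 ± 2.07 RPKM with miR-125b. None of the genes in this paragraph passed the adjustment over the list alone.

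Genes of neutrophil granules and granulocytic maturation were lower as a group, with a median of -0.29 over 20 tested members (camera adjusted p = 0.0149). With an estimated correlation camera's adjusted p was 0.594. Adjusted over the list alone, 5 members were lower, 1 was higher and 14 did not pass, while 0 passed over all genes. S100a8 and S100a9 encode the calcium-binding pair calprotectin. S100a8 (chromosome 3, 90472993 to 90473956) was at 144.3 and 127.6 RPKM in the control libraries and at 10.9 and 0.870 RPKM in the miR-125b libraries, a mean 23.1 times lower. S100a9 was at 459.7 and 247.8 RPKM in control and at 33.0 and 1.92 RPKM with miR-125b, with a log2 fold change of -5.09 that was -3.32 without miR-125b replicate 2. The lactoferrin gene Ltf was at 7.02 ± 2.57 and 0.781 ± 0.489 RPKM (SD, n = 2 each), and Cebpe, a transcription factor of late granulocytic maturation, at 56.5 ± 13.8 and 23.2 ± 1.99 RPKM.

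Ncf1, a subunit of the phagocyte NADPH oxidase with a 7mer-m8 site, was the fifth of the lower members, at 78.5 ± 17.4 RPKM in control and 44.3 ± 2.31 RPKM with miR-125b. The higher member was Mpo, the gene of the primary-granule enzyme myeloperoxidase, at 39.1 and 54.2 RPKM in control and 273.0 and 105.3 RPKM in miR-125b cells. Ncf1 and Mpo fall outside the naming rule's 4 members and were chosen after their values were seen. The list's call ended without control replicate 2, where the median was -0.061 (adjusted p = 0.354), and the median was -0.45 without control replicate 1 and -0.12 without miR-125b replicate 2.

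**Figure D3:**
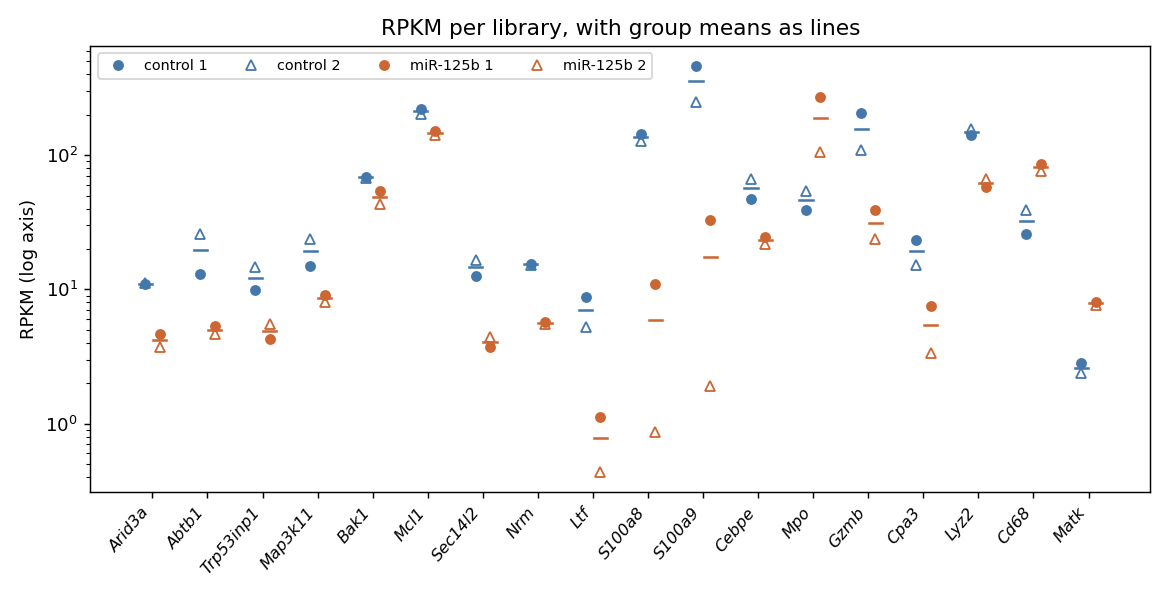
RPKM of 18 named genes (vertical log axis) in each library, with circles for replicate 1, open triangles for replicate 2 and lines for the group means; control is blue and miR-125b orange. S100a8 and S100a9 lie far lower in both miR-125b libraries, which themselves differ from each other, and Mpo, Cd68 and Matk lie higher.

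Markers of other blood lineages did not move one way. Camera and fry's directional test can miss lists whose members move both ways. Fry's mixed test, which counts changes in either direction, passed 2 of the 23 lists. These were the monocyte and macrophage list (adjusted p = 0.0112) and the mast cell and basophil list (adjusted p = 0.00203). Over 9 tested monocyte and macrophage genes the median was -0.031 (camera adjusted p = 0.631). Adjusted over the list alone, the lysozyme gene Lyz2 was lower, at 140.4 and 157.4 RPKM in the control libraries and 58.0 and 66.1 RPKM in the miR-125b libraries, and Cd68 was higher, at 32.5 ± 9.28 and 80.9 ± 6.03 RPKM (SD, n = 2 each). Over 9 mast cell and basophil genes the median was -0.19 (camera adjusted p = 0.321). There 3 members were lower over the list alone. The granzyme gene Gzmb was at 157.9 ± 68.8 RPKM in control and 31.2 ± 10.8 RPKM with miR-125b, the carboxypeptidase gene Cpa3 at 19.2 ± 5.87 and 5.41 ± 2.92 RPKM, and the interleukin gene Il4 at 1.33 and 2.08 RPKM in control and 0 and 0.283 RPKM with miR-125b. The protease gene Prss34 was higher, at 0.330 ± 0.466 and 5.50 ± 4.11 RPKM, as was Ms4a2, the beta chain of the IgE receptor, at 1.26 ± 0.837 and 3.53 ± 0.221 RPKM, which is named outside the rule and was chosen after its values were seen. Il4 and Prss34 had low values and were held by 20 of the 22 alternative analyses. In the simulations most false calls were among genes with fewer than 50 reads. The mast cell list passed camera with genes at 50 reads or more (median -0.20, adjusted p = 0.0247) and at 5 RPKM or more (median -0.21, adjusted p = 0.0410), but its median was 0.058 without miR-125b replicate 1 and 0.0093 without miR-125b replicate 2. With libraries left out, the monocyte and macrophage median ran from -0.24 (without control replicate 1) to 0.083 (without miR-125b replicate 2), and with genes at 50 reads or more it was -0.38.

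Over 10 erythroid and megakaryocyte genes the median was 0.0098 and camera's direction was downward (adjusted p = 0.823). This list's median was 0.12 without miR-125b replicate 1 (adjusted p = 0.00967) and -0.20 without miR-125b replicate 2 (adjusted p = 0.0120), so its direction depended on the library. Of 22 lymphoid markers only Cd79b passed the filter on low values and was tested (camera adjusted p = 0.235). Its log2 fold change of 0.79 ± 0.40 (SE) was 1.41 without miR-125b replicate 1 and 0.17 without miR-125b replicate 2. Of 20 stromal and fibroblast markers, Thy1 and Pdgfrb were tested. Thy1 was higher over the list alone, at 0.489 ± 0.329 and 1.75 ± 0.793 RPKM, with a log2 fold change of 0.87 that was 0.57 without miR-125b replicate 2. It was held by 20 of the 22 alternative analyses, and with genes at 50 reads or more the list kept 1 member. The median of Thy1 and Pdgfrb was 0.25 (camera adjusted p = 0.480) and -0.038 without control replicate 1. Over all genes 0 members of these lists passed.

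Genes of the p53 response were lower as a group, with a median of -0.30 over 25 members, 20 of them lower (camera adjusted p = 0.00271, and adjusted p = 0.594 with an estimated correlation). The cell-cycle inhibitor gene Cdkn1a was at 274.7 ± 77.9 RPKM in control and 165.6 ± 0.128 RPKM with miR-125b (SD, n = 2 each), and Aen, an apoptosis-enhancing nuclease gene, at 33.5 ± 1.24 and 22.8 ± 0.850 RPKM. Genes of IL-3 and JAK-STAT signalling had a median of -0.26 over 29 members, 23 of them lower (camera adjusted p = 0.00382, and adjusted p = 0.594 with an estimated correlation). Csf2rb2, a beta chain of the interleukin-3 receptor, was at 32.3 ± 4.21 and 18.0 ± 6.56 RPKM, the phosphatase gene Dusp6 at 30.4 ± 4.99 and 17.9 ± 0.405 RPKM, while the kinase gene Tyk2 differed by -0.70 ± 0.22 (SE). In neither list did a member pass over all genes or over the list alone. The p53 list's adjusted p was 0.0504 without miR-125b replicate 1, and the IL-3 list's median was -0.43 without control replicate 1 and -0.10 without control replicate 2 (adjusted p = 0.296).

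Stem and progenitor regulators were lower as a group, with a median of -0.28 over 21 members, 17 of them lower (camera adjusted p = 0.0182, and adjusted p = 0.594 with an estimated correlation). Etv6, a transcriptional repressor with a 7mer-m8 site, was at 18.9 ± 3.41 RPKM in control and 11.5 ± 1.18 RPKM with miR-125b, and Lyl1 was at 61.7 ± 11.5 and 42.6 ± 3.77 RPKM (SD, n = 2 each). Mecom, the gene of the transcription factor EVI1, was higher, at 163.0 ± 0.185 and 239.9 ± 54.8 RPKM. No member passed over the list alone, and the median was -0.070 without control replicate 2 (adjusted p = 0.523) and -0.23 without miR-125b replicate 1 (adjusted p = 0.116). It was -0.17 without miR-125b replicate 2, and without a filter on low values the call also ended (median -0.17, adjusted p = 0.0585).

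Ribosomal protein genes had a median of -0.17 over 42 members, 29 of them lower (camera adjusted p = 0.0149, and adjusted p = 0.594 with an estimated correlation). The members with the smallest p, Rpl28 with a log2 fold change of -0.89 ± 0.25 (SE) and Rpl10a at 10.2 ± 0.930 and 6.22 ± 0.659 RPKM, are uncertain because ribosomal protein genes have many near-identical pseudogenes. The call ended with a correction for exon length, at a median of -0.12 (adjusted p = 0.0682), with genes at 50 reads or more, at -0.093 (adjusted p = 0.215), and without control replicate 2, at -0.076 (adjusted p = 0.0697). It also ended without miR-125b replicate 1 (median -0.12, adjusted p = 0.185) and with genes at 5 RPKM or more (median -0.14, adjusted p = 0.203).

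Type I interferon response genes were lower as a group, with a median of -1.29 over 30 members, all of them lower in the group means (camera adjusted p = 8.16e-12, and adjusted p = 0.594 with an estimated correlation, which was 0.893 in this list). At an unadjusted p under 0.05, 8 were lower, and 0 passed over the list alone. Ifi44 was at 63.3 ± 34.6 RPKM in control and 14.2 ± 11.7 RPKM with miR-125b, and the nucleic acid sensor gene Zbp1 at 55.2 ± 46.1 and 10.5 ± 10.3 RPKM (SD, n = 2 each). The list's medians did not separate the groups by library. Relative to the control mean, the list's median was -0.60 in control replicate 1 and 0.60 in control replicate 2, and -0.48 and -2.09 in miR-125b replicates 1 and 2. The median log2 fold change was -0.54 without control replicate 2, -2.09 without miR-125b replicate 1 and -0.48 without miR-125b replicate 2, and the call held in each of these.

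Genes of mitosis were higher as a group, with a median of 0.28 over 30 members, 28 of them higher (camera adjusted p = 5.30e-05, and adjusted p = 0.594 with an estimated correlation). The centromere protein gene Cenpf was at 9.90 ± 3.09 RPKM in control and 18.7 ± 1.27 RPKM with miR-125b, and the kinesin gene Kif23 at 12.5 ± 4.25 and 20.9 ± 4.10 RPKM (SD, n = 2 each). Genes of DNA replication had a median of 0.17 over 39 members, 33 of them higher (camera adjusted p = 0.0142, and adjusted p = 0.710 with an estimated correlation). Rfc4, a subunit of the clamp loader, was at 18.0 ± 5.78 and 27.6 ± 4.48 RPKM, while the flap endonuclease gene Fen1 was lower, at 99.4 ± 13.1 and 61.9 ± 15.5 RPKM. No member of either list passed over the list alone. Without control replicates 1 and 2 in turn, the mitosis median was 0.54 and 0.15, and the DNA replication median 0.42 and -0.0026, the last with an adjusted p of 0.696.

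Genes of cholesterol biosynthesis were higher as a group, with a median of 0.36 over 23 members, 15 of them higher and 8 lower (camera adjusted p = 0.00967, and adjusted p = 0.594 with an estimated correlation). At an unadjusted p under 0.05 in limma's test, 8 members were higher and 0 lower. Pmvk, the phosphomevalonate kinase gene, was at 23.5 ± 5.84 RPKM in control and 43.8 ± 0.497 RPKM with miR-125b, and Acat2 at 13.8 ± 0.0181 and 26.8 ± 9.04 RPKM (SD, n = 2 each). Fdps, the farnesyl diphosphate synthase gene, had a log2 fold change of 0.62 ± 0.18 (SE). Genes of the unfolded protein and amino acid response had a median of 0.29 over 29 members, 22 of them higher (camera adjusted p = 0.00582, and adjusted p = 0.594 with an estimated correlation). The chaperone gene Hsp90b1 was at 417.0 ± 116.8 and 708.3 ± 5.10 RPKM, and the disulfide isomerase gene Pdia6 at 177.8 ± 24.5 and 293.6 ± 29.5 RPKM. No member of either list passed over the list alone. The unfolded protein median was 0.48 and 0.14 without control replicates 1 and 2 in turn, and the cholesterol call ended without control replicate 1 (median 0.28, adjusted p = 0.0833) and without miR-125b replicate 2 (median 0.17, adjusted p = 0.13).

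Lysosomal genes had a median of 0.23 over 29 members, 21 of them higher (camera adjusted p = 0.0149, and adjusted p = 0.655 with an estimated correlation). The cathepsin gene Ctsz was at 192.5 ± 16.7 RPKM in control and 341.5 ± 17.0 RPKM with miR-125b, and Asah1, the acid ceramidase gene, at 17.8 ± 1.55 and 29.2 ± 0.0203 RPKM (SD, n = 2 each). The sialidase gene Neu1, which carries an 8mer, was lower, at 10.4 ± 3.06 and 4.18 ± 0.252 RPKM. Glycolysis genes had a median of 0.22 over 23 members, 18 of them higher (camera adjusted p = 0.0182, and adjusted p = 0.594 with an estimated correlation), with Tpi1, the triosephosphate isomerase gene, at 201.1 ± 35.1 and 324.4 ± 20.5 RPKM and Pdk1 at 18.2 ± 3.63 and 27.4 ± 2.70 RPKM. Genes of the respiratory chain had a median of 0.16 over 36 members, 27 of them higher (camera adjusted p = 0.0160, and adjusted p = 0.655 with an estimated correlation), with Uqcrc1 at 89.1 ± 14.7 and 128.2 ± 21.6 RPKM. No member of these lists passed over the list alone. The lysosome median was 0.040 without control replicate 1 (adjusted p = 0.820), 0.38 without control replicate 2 and 0.23 without miR-125b replicate 1 (adjusted p = 0.105), and its call ended without a filter on low values (adjusted p = 0.0547). For glycolysis the call ended without control replicate 1 (median 0.15, adjusted p = 0.609), miR-125b replicate 1 (0.19, adjusted p = 0.0504) and miR-125b replicate 2 (0.26, adjusted p = 0.0922), and without a filter on low values (0.22, adjusted p = 0.114). For the respiratory chain the median was 0.26 without control replicate 1, and the call ended without control replicate 2 (0.056, adjusted p = 0.347) and miR-125b replicate 2 (0.11, adjusted p = 0.181).

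**Figure D4:**
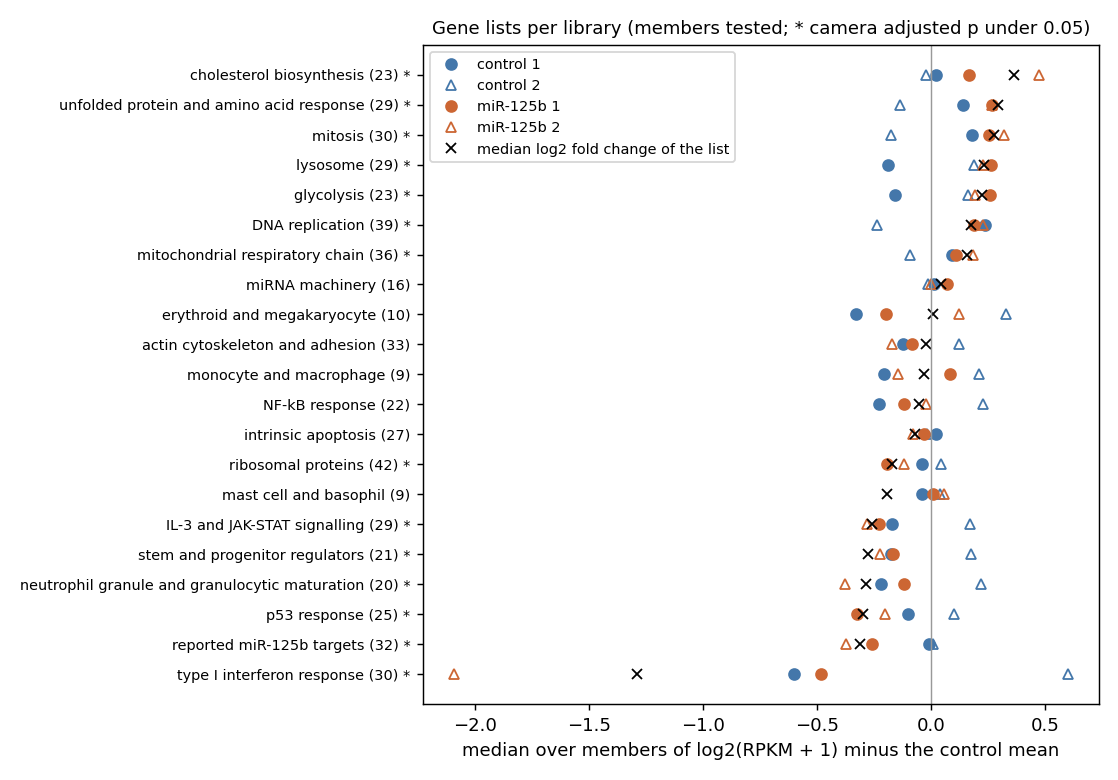
Median over each list's members of log2(RPKM + 1) minus the control mean (horizontal axis) in each library, with crosses for the median log2 fold change of the list; numbers in brackets are members tested and asterisks mark camera adjusted p under 0.05 with the preset correlation. The reported miR-125b targets lie at -0.26 and -0.37 in the miR-125b libraries and near 0 in both controls, whereas the interferon list differs about as much within the groups as between them. The groups also overlap in other lists with an asterisk. DNA replication lies at 0.24 and -0.24 in the controls and 0.19 and 0.23 with miR-125b. The neutrophil list lies at -0.22 and 0.22, then -0.12 and -0.38, and the stem and progenitor list at -0.18 and 0.18, then -0.17 and -0.23.

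The remaining lists did not pass camera. Intrinsic apoptosis genes had a median of -0.070 over 27 members (adjusted p = 0.0896), with Casp6, the gene of an executioner caspase, at 27.7 ± 0.693 RPKM in control and 19.3 ± 4.32 RPKM with miR-125b. NF-kB response genes had a median of -0.054 over 22 members (adjusted p = 0.463), with the cytokine gene Il6 differing by -0.81 ± 0.19 (SE), and passed only without control replicate 1 among the left-out libraries (median -0.31, adjusted p = 0.00919). Without control replicate 2 the NF-kB median turned to 0.10, that of the miRNA machinery to -0.050 and that of actin and adhesion to 0.082, while with libraries left out the apoptosis median ran from -0.15 to -0.033. The medians were 0.044 over 16 genes of the miRNA machinery (adjusted p = 0.703), among them Dicer1 at 10.6 ± 1.85 and 13.5 ± 0.818 RPKM, and -0.022 over 33 genes of the actin cytoskeleton and adhesion (adjusted p = 0.550), among them S100a10 at 88.4 ± 12.6 and 55.6 ± 5.54 RPKM (SD, n = 2 each).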

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

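Scaling factors, the GC correction without a block, its combination with a left-out library, other rows per gene and minimum lengths or levels were tried after the data had been seen; the other alternatives were planned. The planned negative-binomial count tests and their scalings were not run because the deposited values are RPKM, although the recovered reads could have served for them. Scaling by library size is the deposited scaling itself. The seed match ranked first among all 7-mers in each of the 22 alternative analyses. The shift of genes with a site kept its direction and stayed past camera's threshold with the preset correlation in all of these, from -0.16 to -0.042. It missed the threshold with an estimated correlation (-0.12, p = 0.060), as did genes with sites in the coding sequence only (-0.049, p = 0.184). The 7mer-A1 class passed camera after the GC correction (-0.053) and with the replicate block with GC and length correction (-0.055); the cause was not tested.

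The replicate block called 12 genes, 6 of them list members, and with GC and length correction 4 and 2; the labels do not tie the replicate numbers, deviations of same-numbered libraries correlated at 0.021, and the block changed no call of a gene list. Leaving out 1 library in turn gave between 0 and 91 changed genes, between 0 and 32 of them list members, and between 8 and 12 lists past camera, where 1 group then holds a lone library assumed to vary like the others. With the GC correction and without control replicate 2 there were 1 gene and 8 lists. The cause of these differences was not tested. Of the 14 lists, 0 passed with an estimated correlation and 0 with fry's directional test. The estimated version rests on 2 residual degrees of freedom, so its lack of calls does not by itself show correlation between genes. In the reported targets the estimated correlation (-0.019) was below the preset 0.01, yet camera's p rose from 2.23e-05 to 0.040. With the preset correlation, 4 passed in every setting: the reported targets, interferon, mitosis and unfolded protein lists. With libraries left out, the DNA replication median ran from -0.0026 (without control replicate 2, and -2.6e-04 with the GC correction) to 0.42, and the erythroid median from -0.48 to 0.23, with calls in opposite directions without miR-125b replicate 1 (0.12) and 2 (-0.20). Stricter or looser thresholds and a 2-fold minimum left the count of changed genes at 0.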

Other observations

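All predictions weighed in this part were written after the results they bear on had been seen; the matched random lists and the left-out library had been planned, and the other tests were chosen only after the results. The 7-mers that followed the seed match in the ranking also resembled it. Places 4 to 7 were held by ACTCAGG (z = -7.13), CTCAGGA (z = -6.39), CTCAGGT (z = -5.65) and CCTCAGG (z = -5.14), which all contain the 6 bases CTCAGG of the seed match. Genes with CTCAGGG were not removed from these classes, so the classes overlap. Among the 3 ways to split the 4 libraries into pairs, the real one gave 967 genes at an unadjusted p under 0.05 and the highest other gave 308, and 3 splits are too few for a share under 0.05.

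The first pattern is that mRNAs with a miR-125b site were lower in the miR-125b libraries. The length of the 3′ UTR and expression level do not account for it, since the median of these genes (-0.0692) lay below all of the matched random lists. The GC trend of control replicate 2 is not its whole cause, since the difference in medians was -0.106 after the GC correction with all libraries. Without control replicate 2 the difference was -0.0619, nearer 0 than with all libraries. It was -0.0618 when the GC correction was also made, so the fall without that library was not one that the GC correction removed. Repression through the miR-125b seed predicts that the seed match leads the ranking in every pairing between the groups and in none within them, which was found, the weakest z between groups being -8.5, although the seed match also ranked 18 between the miR-125b libraries. As a hypothesis found and tested on the same data, this is consistent with direct repression of many mRNAs by small amounts.

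The second pattern is the lower level of type I interferon genes. The GC trend of control replicate 2 does not account for it, since the median was -1.31 after the GC correction. Differences between cultures of the same group stay open: control replicate 2 exceeded control replicate 1 by a median of 1.20, and miR-125b replicate 1 exceeded replicate 2 by 1.59, while the group means differed by 1.29. Replicate 1 of the 2 groups differed by a median of 0.051. With 2 libraries per group an effect of miR-125b and differences between single cultures cannot be told apart.

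The third pattern is that the seed matches of let-7, miR-223, miR-155, miR-142-3p, miR-16 and miR-21 had a mean z of 1.46, where random sets of 7-mers with the same GC counts had a mean of 0.331 and 24 of 10000 reached 1.46. It rests on control replicate 1: the mean was 0.759 without that library (688 of 10000 sets as high), and 1.68 and 1.905 in its pairings with the miR-125b libraries, against 0.498 and 0.918 with control replicate 2, 0.773 between the controls and 0.852 between the miR-125b libraries. miR-142-3p, 10th most positive of 16020 with all libraries, likewise had a z of 4.16 and 3.95 against control replicate 1, 1.47 and 1.87 against control replicate 2, and 1.65 between the controls. The GC trend of control replicate 2 does not account for the mean, which was 1.96 without that library. Competition of miR-125b with other miRNAs, an effect of the miR-142-3p and miR-21 sites alone and differences between cultures are all left open, since the other 4 seeds had a mean of 0.715, which 230 of 10000 random sets reached after their 2 highest 7-mers were also taken out (a comparison chosen after 1746 of 10000 sets of 4 with none taken out had reached it).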
